A study of Caenorhabditis elegans with 2 samples.

How the data were processed

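Chromatin immunoprecipitation sequencing (ChIP-seq) of AHA-1 fused to green fluorescent protein was analysed from peak lists deposited for 2 biological replicates of whole L1 larvae of C. elegans strain OP124. Replicate numbers were taken from the labels, which also gave a fragment size range of 150 to 350 bp. Both replicates formed 1 group. There was no second group, so no difference between conditions was tested. The labels call the replicates biological and do not describe how they were grown.

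The authors deposited narrowPeak lists on the ce10 and ce11 assemblies of 3 kinds. Relaxed lists of peaks and background were made for each replicate and for the replicates pooled, each against a control, and a thresholded list was kept from the pooled list by the irreproducible discovery rate (IDR), per the descriptive text deposited with the samples. The aligner, peak caller, IDR threshold, read depth and strain of the control were not given in the sources used here. The control itself was not analysed here. The signal value of each peak is the authors' deposited signal, as the peak caller wrote it relative to a control, and its scale is not stated, so it was used to describe and rank peaks within a list. Between the replicate lists it was used for correlations, which need no common scale, and levels were not tested against each other. The deposited lists also give a −log10 q-value per peak; it reached 3.33 in the pooled list on ce11, a value shared by 1074 regions including all 530 thresholded peaks, so it was not used for ranking. The lists on ce11 held 530 thresholded peaks with a median width of 316 bp, 30000 pooled regions, 24611 regions of replicate 1 and 18195 of replicate 2. The thresholded peaks were exactly the 530 pooled regions of highest signal: the lowest kept was 18.4 and the highest left out 18.3.

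Peaks on ce11 were compared with the Ensembl release 115 annotation of the same assembly and with its genome sequence, which were used for 19973 protein-coding genes and 46890 genes of all kinds on 6 chromosomes. Mitochondrial sequence was not used here. Coordinates are 1-based. A summit was assigned to every gene with an annotated transcript start, alternative starts inside the gene included, such that the summit lay from 1000 bp upstream to 200 bp downstream of it. Summits outside these windows were classed as coding exon, UTR, intron, non-coding gene or pseudogene, or intergenic, in that order. Lists on ce10 were used only for counts, replicate overlap, correlation and chromosome shares, the last against ce11 lengths, and no coordinates were converted.

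Promoter share was compared with 1000 random placements of the summits within their chromosomes (one-sided randomisation p) and, by a two-sided Fisher's exact test, with pooled relaxed regions outside the thresholded peaks. Peaks per chromosome were compared with sequence length by a two-sided exact binomial test. The 6 words GCGTG, ACGTG, CACGTG, other CANNTG, WGATAR and GAGAGA, and all words of 6 bp on both strands, were sought within 50 bp of each summit and in windows 400 bp to either side. Summits were compared with 1 flank drawn at random by a two-sided exact McNemar test, and the printed flank share is the mean of both flanks. Membership of 29 gene lists was tested with a two-sided Fisher's exact test against all other protein-coding genes, or all other genes for RNA classes. Lists of gene families were made from symbol prefixes followed by a number, with single symbols added to some. Family members under other symbols were counted among the other genes. A symbol on the hypodermis list (1 in all lists) matched no gene. Neighbouring genes can share a peak, so members of a list are not fully independent. Replicate overlap was the share of the top 530 regions of one replicate that overlap the top 530 of the other by at least 1 bp, against 1000 random placements. P-values were adjusted by Benjamini-Hochberg within each family (6 chromosomes, 6 words, 2080 words of 6 bp, 29 lists), with a threshold of 0.05. Intervals are exact (Clopper-Pearson) at 95%, over peaks or genes. Because depth is unknown, no interval for counting error in reads was given, and for lists with no member the upper limit is 3 divided by the number of members.

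Genes named in the text followed a rule fixed, with the lists, tests and main alternatives, before the data were examined: aha-1 and all members of the bHLH-PAS and hypoxia lists; the genes at the 20 strongest peaks, by promoter window or else nearest start; and up to 4 members of every other list by signal. The tRNA genes it selects have only identifiers in the annotation used and are not named. The peaks named with aha-1, rpl-20, eef-1A.1, hsp-60, hsp-90, nhr-142, col-38, vha-8 and the farther gene of each pair that shares a peak lay nearer to the start of another protein-coding gene. The egl-9 peak was found under the nearest-start part of this rule. Alternatives were the ce10 lists, the stronger peaks alone (265 of 530), the top 530 regions of each replicate alone (described as leaving out the other replicate), other overlap rules, other promoter and motif windows, gene share in place of length, nearest starts only and 10 sets of ranked regions in place of 5. Those chosen after seeing the data were restriction to the 268 thresholded peaks in the top 530 of both replicates, restriction of gene lists to genes with a relaxed region in the promoter window, use of the outermost start of each gene only for promoter share and gene lists, and a correlation without the 2 strongest peaks.

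Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9. The code was tested on simulated data first. Of 530 simulated peaks, the 300 placed in promoter windows were all counted there, and 200 of 200 planted ACGTG words were found. In a list of 40, 20 of 20 planted genes were counted. These 20 were taken from the genes already assigned a simulated peak, so that count did not test the assignment.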

Results

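The series profiled where AHA-1 binds DNA in first-stage (L1) larvae of the nematode Caenorhabditis elegans. AHA-1 is the worm ortholog of ARNT, the common partner of basic helix-loop-helix PAS (bHLH-PAS) transcription factors such as the hypoxia-inducible factor HIF-1 and the aryl hydrocarbon receptor AHR-1. Strain OP124 carries an integrated transgene that expresses AHA-1 fused to green fluorescent protein, and chromatin from whole larvae of mixed sex was immunoprecipitated for the fusion protein and sequenced (ChIP-seq). The labels gave 1 group of 2 biological replicates and no second condition, so the comparisons were between bound and unbound parts of the genome, between gene groups and between the replicates. The files were lists of peaks, and the number of reads behind them is unknown. Intervals below are exact binomial intervals over peaks or genes and do not cover variation between animals.

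AHA-1 peaks were found at 530 sites on the ce11 assembly in the authors' thresholded list, and the strongest of them lay upstream of egl-9, which encodes the oxygen-dependent prolyl hydroxylase that marks HIF-1 for degradation. That peak, on chromosome V from 10466664 to 10466911, had a pooled signal value of 254 against a median of 26.9 over all 530 peaks, and it ranked 1 in both replicates, with signal values of 167 and 94.9. Its summit was 1732 bp upstream of the nearest egl-9 start, in sequence annotated as non-coding gene or pseudogene. The peak of rank 2 lay on chromosome V from 4131581 to 4131789, in the intergenic sequence 206 bp upstream of nhr-57, a nuclear hormone receptor gene known to respond to HIF-1. Its pooled signal value was 118, and its ranks were 2 and 5 in the replicates.

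Beyond these, 4 of the 20 strongest peaks lay in promoters of genes on the ribosomal protein list and 1 in that of a gene on the translation factor list, both made from symbol prefixes. The ribosomal protein genes were rpl-3 (chromosome III from 3867487 to 3867644, signal 115.2), rpl-15 (chromosome IV from 654849 to 654992, signal 89.3), rpl-35 (signal 77.3) and rpl-20 (signal 76.2). The last of these peaks was nearer to Y17G9B.5, at 170 bp, than to rpl-20, at 292 bp. The translation factor gene iff-2 had a peak 73 bp upstream of its start, with signal 82.7, and cox-5A, which encodes a subunit of cytochrome c oxidase, had one 285 bp upstream with signal 65.7. The gene of the sulfide:quinone oxidoreductase, sqrd-1, had a peak over its start on chromosome IV from 14219784 to 14219927, in the UTR, with signal 85.1. Some of these promoter windows were shared, those of rpl-15 with K11H12.8 and iff-2 with F54C9.14. Further promoters in this group were those of tasp-1, a threonine aspartase gene, with K01G5.10, cdc-48.1, an AAA ATPase gene, puf-9, eelo-2, sec-61.G with F32D8.13, wip-1 with larp-1, and drr-2 with set-16. Of the 20 strongest peaks, 15 had their summit in a protein-coding promoter window, from 1000 bp upstream to 200 bp downstream of a start. The exceptions besides egl-9 were an intron on chromosome X (4142202 to 4142401, signal 116) whose nearest start was that of ZK470.4, an intron of hlh-30 on chromosome IV (4026062 to 4026230, signal 102), 928 bp downstream of the nearest annotated start of that basic helix-loop-helix factor gene, and sites on X whose nearest starts were F09E10.1 and K02D3.1. All 20 were among the 25 strongest regions of replicate 1, and their lowest rank in replicate 2 was 101.

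**Figure D1:**
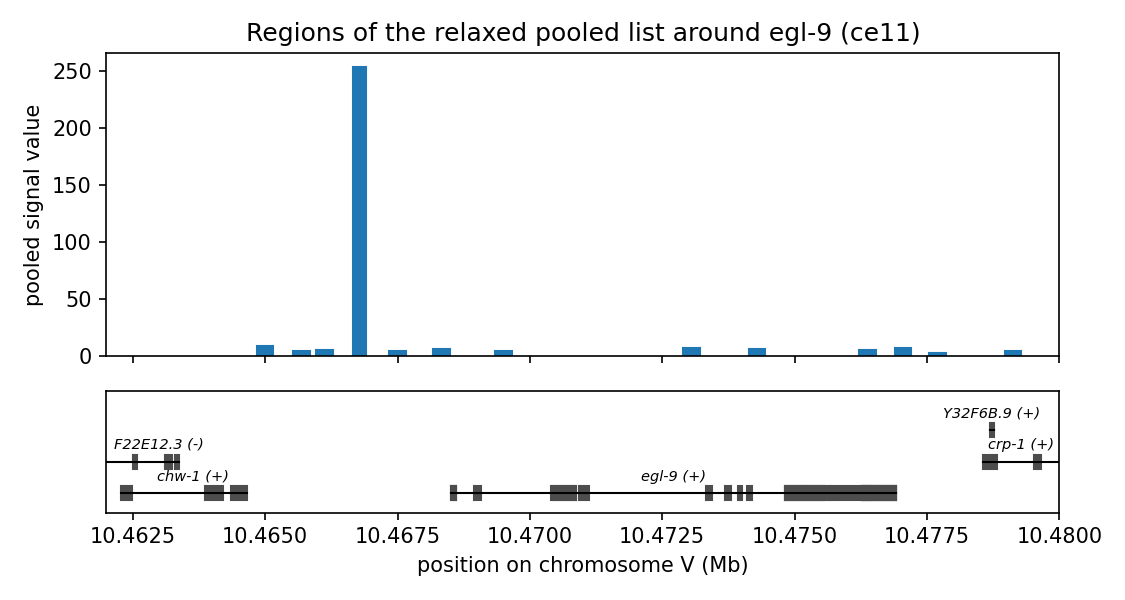
Regions of the pooled relaxed list around egl-9 on chromosome V of ce11. The upper panel gives the signal value of each region as a bar over its position in Mb (the peak upstream of egl-9 has 254), and the lower panel the protein-coding genes with exons as boxes and the strand in brackets, without non-coding genes.

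HIF-1 binds DNA as a dimer with AHA-1, which made the genes of the hypoxia response a question of their own. Of the 13 genes on the hypoxia response list, 4 had a thresholded peak in the promoter window (30.8%, interval 9.09 to 61.4%), against 2.72% of the other protein-coding genes, with an odds ratio of 15.9 and an adjusted p of 0.00134 in Fisher's exact test. These were nhr-57, sqrd-1, rhy-1 and F22B5.4. The peak of rhy-1, a membrane protein gene that restrains HIF-1, lay 964 bp upstream on chromosome II from 9160257 to 9160572, with a pooled signal of 40.8 and replicate signals of 22.4 and 15.9. F22B5.4, a hypoxia-induced gene, had its peak in one of its own introns, on chromosome II from 8451514 to 8451829. It lay 449 bp upstream of an alternative start inside the gene and 1962 bp downstream of the outermost start, with a pooled signal of 22.3 and replicate signals of 16.1 and 5.93. The replicate signals of sqrd-1 were 49.9 and 32.1, and those of nhr-57 were 84.1 and 34.03. With the window widened to 2000 bp upstream and 500 bp downstream, egl-9 joined them (38.5%, adjusted p 0.000236). With the outermost start of each gene only, an alternative chosen after seeing the data, 3 of the 13 had a peak (23.1%, adjusted p 0.0148).

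The other 8 hypoxia genes had no thresholded peak that close. The nearest peak to cysl-2, a cysteine synthase family gene, was 2534 bp upstream and was not listed in replicate 2, and that to the related cysl-1 was 4230 bp upstream. For smf-3, a metal transporter gene, the distance was 16691 bp, and for ethe-1, a sulfur dioxygenase gene, 64161 bp. The nearest peaks to vhl-1, which encodes the von Hippel-Lindau ortholog, cah-4, phy-2 and the ferritin gene ftn-1 were 100162 bp or more away. The pooled relaxed list holds background as well as peaks, with signals from 2.88 upward and a median of 4.27 over 30000 regions. In it, ftn-1 had a promoter region with signal 9.95 (rank 1551), ethe-1 one with 6.52 (rank 4826) and cah-4 one with 3.502 (rank 22132). No region lay in the promoter windows of vhl-1, phy-2, smf-3, cysl-1 or cysl-2.

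Among the bHLH-PAS genes, aha-1 itself had a promoter peak and its 4 relatives had none (1 of 5, odds ratio 8.91, adjusted p 0.393 in Fisher's exact test). The aha-1 peak lay 234 bp upstream on chromosome I from 10197073 to 10197388, in intergenic sequence, with a pooled signal of 27.3 and rank 255. It was nearer to the start of C25A1.15, 90 bp away, so that with nearest starts only the list's single member with a peak was hif-1 and not aha-1 (adjusted p 0.345). Its signal was 24.7 in replicate 1, where it ranked 120, and 3.196 in replicate 2, where it ranked 7047. The nearest peak to hif-1 was 1967 bp upstream on chromosome V from 20778282 to 20778597, with a pooled signal of 36.9 and replicate signals of 27.1 and 5.19. With the window of 2000 bp upstream and 500 bp downstream it counted beside that of aha-1, and the list had 40% of its members and an adjusted p of 0.0356. The nearest peaks to hlh-34, ahr-1 and cky-1 were 28664, 95336 and 100240 bp from their starts. Of the other bHLH genes, 2 of 35 had a promoter peak, hlh-11 (signal 24.7) and mdl-1 (signal 24.0), and the list did not pass the test (adjusted p 0.526).

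**Figure D2:**
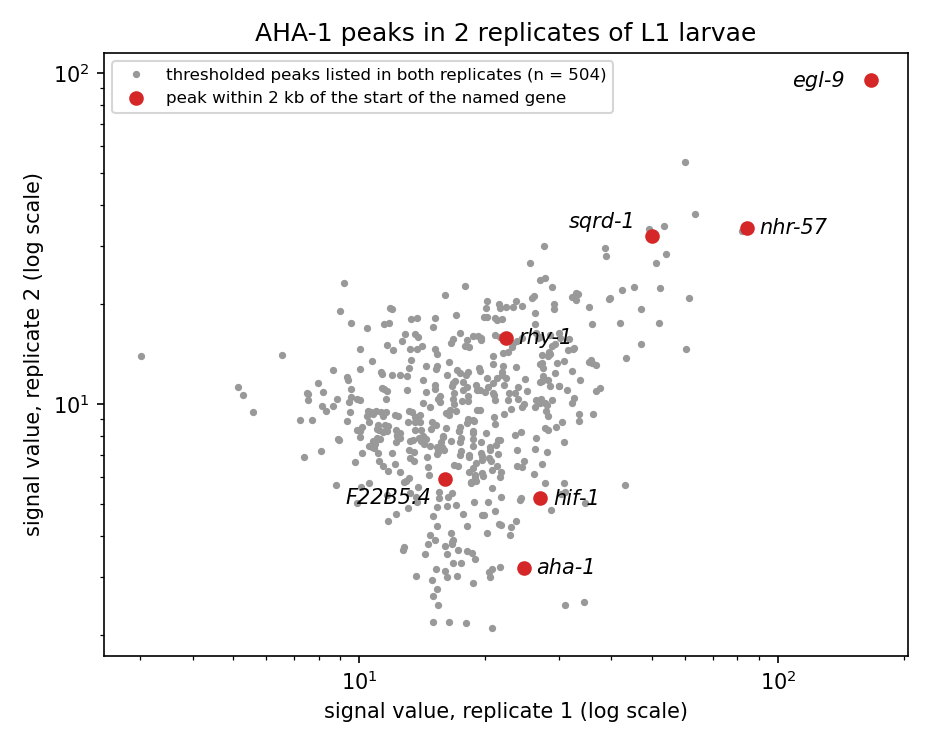
Signal values of the 504 thresholded peaks listed in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both on log scales. Grey points are peaks and red points the peaks within 2 kb of the start of a named hypoxia or bHLH-PAS gene; egl-9 is at the upper right with 167 and 94.9, and aha-1 at 24.7 and 3.196.

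Genes of protein synthesis and of the respiratory chain carried AHA-1 peaks far more often than other genes. Of 81 ribosomal protein genes, 33 had a promoter peak (40.7%, interval 29.9 to 52.2%), against 2.58% of the other protein-coding genes, with an odds ratio of 26.0 and an adjusted p of 4.58e-29. They divided into 19 of 47 large-subunit genes named rpl, 14 of 31 small-subunit genes named rps and 0 of 3 acidic protein genes named rla, and rested on 31 distinct peaks with a median rank of 265. Translation factors had 9 of 38 (23.7%, odds ratio 11.2, adjusted p 4.65e-06), among them the elongation factor genes eef-1A.1 (signal 39.5) and eef-1A.2 (signal 36.7) and the initiation factor gene eif-3.C (signal 39.4). Respiratory chain genes had 11 of 39 (28.2%, odds ratio 14.2, adjusted p 4.67e-08), with sdha-1 of succinate dehydrogenase at signal 44.6, atp-1 of the ATP synthase at 43.2 and cox-5B of cytochrome c oxidase at 41.1 after cox-5A. That list holds the prefixes nuo, cox, atp, ucr and cyc and a few single symbols. Genes with symbols that begin with ndu were counted among the other genes, and some of them had peaks. With each summit given to its nearest start only, ribosomal protein genes were at 23.5% (odds ratio 12.4, adjusted p 2.68e-12) and respiratory chain genes at 17.9% (odds ratio 8.64, adjusted p 0.000325). Ribosomal protein genes were at 20.99% both among the 265 strongest peaks and among the 268 in the top 530 of both replicates, and translation factors at 15.8 and 13.2%. These sets hold fewer peaks, and the share of genes outside the ribosomal list was also lower, at 1.26 and 1.27%. The odds ratios were 20.8 and 20.7 for ribosomal protein genes and 14.1 and 11.3 for translation factors.

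Heat shock protein genes also stood above the rest, with 7 of 22 (31.8%, odds ratio 16.8, adjusted p 7.60e-06). The strongest were the chaperone genes hsp-60 (signal 59.8, 616 bp upstream), hsp-90 (signal 51.4), hsp-1 (signal 45.2, 382 bp upstream) and hsp-3 (signal 36.3, 52 bp upstream). The hsp-90 summit lay in an intron of the gene, 390 bp upstream of an internal start and 852 bp downstream of the outermost one. Several of these peaks lay closer to a neighbouring start, and with each summit given to its nearest start only, 13.6% of the list had a peak, with an adjusted p of 0.0608. The share was 18.2% among the top peaks of replicate 2 alone (odds ratio 9.48, adjusted p 0.00854). It was the same among the 268 peaks (odds ratio 16.5, adjusted p 0.00113). Proteasome genes had 2 of 33, rpn-3 (signal 34.5) and rpt-6 (signal 21.8), with an adjusted p of 0.526. Vacuolar ATPase genes had 1 of 20, vha-8 (signal 21.5, adjusted p 0.667), which became 15% with an adjusted p of 0.0335 among the top peaks of replicate 2 alone.

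Genes of snoRNAs and snRNAs had peaks more often than all other genes, and the classes of small RNA were not compared with each other. Genes of snoRNAs had a peak at 26 of 346 (7.51%, odds ratio 4.88, adjusted p 4.42e-09) and snRNA genes at 10 of 129 (7.75%, odds ratio 4.97, adjusted p 0.000335), the latter including the spliced leader genes sls-2.4 (signal 54.1), sls-2.1 (signal 46.3), sls-2.8 (signal 32.5) and sls-2.2 (signal 30.3). The peaks of 19 of the 26 snoRNA genes and 7 of the 10 snRNA genes also lay in a protein-coding promoter window, such as the peak at rpl-15, in the windows of the snoRNA genes K11H12.12 and K11H12.13, and those at iff-2 and cdc-48.1, in the windows of F54C9.12 and C06A1.9. With nearest starts only, snoRNA genes were at 3.47% (odds ratio 3.29, adjusted p 0.00246), and with a window from 500 bp upstream to 100 bp downstream at 4.05% (adjusted p 0.000527). Among the 265 strongest peaks, snoRNA genes were at 4.05% (odds ratio 5.29) and snRNA genes at 3.88% (odds ratio 4.96, adjusted p 0.0175). tRNA genes had 7 of 612 (odds ratio 0.674, interval 0.269 to 1.40, adjusted p 0.667) and microRNA genes 6 of 261 (odds ratio 1.38, adjusted p 0.667), with cel-mir-354 (signal 54.1), cel-mir-5549, cel-mir-52 and cel-mir-54 the strongest. The peaks of 2 of the 7 tRNA genes and 2 of the 6 microRNA genes also lay in a protein-coding promoter window. The cel-mir-354 summit was nearer to a protein-coding start, at 168 bp, than to its own, at 841 bp. The odds ratio of microRNA genes was 2.89 among the 265 strongest peaks (adjusted p 0.0751) and 0.694 with nearest starts only (adjusted p 1).

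Markers of single tissues had few peaks, as did protein-coding genes in general. Outside each of these lists, 2.73 to 2.74% of protein-coding genes had a promoter peak. Lists this short do not show a lack of peaks against that share. No promoter peak was found at the 14 pharynx, 15 hypodermis, 16 pan-neuronal, 18 neuron identity, 14 body wall muscle or 16 germline genes, nor at the 9 genes of oxygen-sensing neurons, and these lists are too short for the counts of 0 to exclude shares of up to 16.7 to 33.3%. Of 20 intestine genes, the gut esterase gene ges-1 had a peak (signal 27.4, adjusted p 0.667 for the list). Nuclear hormone receptor genes had 4 of 269 (odds ratio 0.534, adjusted p 0.526), namely nhr-57, nhr-47, nhr-142 and nhr-32. Core histone genes had 3 of 72 (his-37, his-67 and his-68, adjusted p 0.667), homeobox genes named ceh 1 of 63 (ceh-38, adjusted p 1) and collagen genes named col 1 of 156 (col-38, adjusted p 0.393). The C-type lectin genes were lower than the rest with 0 of 240, which allows up to 1.25% (adjusted p 0.00804). That call ended with the 265 strongest peaks (0 of 240 against 1.36% of others, adjusted p 0.238). It also ended with the top peaks of replicate 1 alone (0.417%, adjusted p 0.0850). In alternatives chosen after seeing the data, it ended with the 268 peaks (0 of 240 against 1.36%) and with genes that had a relaxed region (0 of 59). In the main test, 2.77% of the others had a peak. Cytochrome P450 genes (0 of 74, adjusted p 0.526), UDP-glucuronosyltransferase genes (0 of 67, adjusted p 0.526) and glutathione S-transferase genes (0 of 44, adjusted p 0.876) had no peak and did not pass the test.

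**Figure D3:**
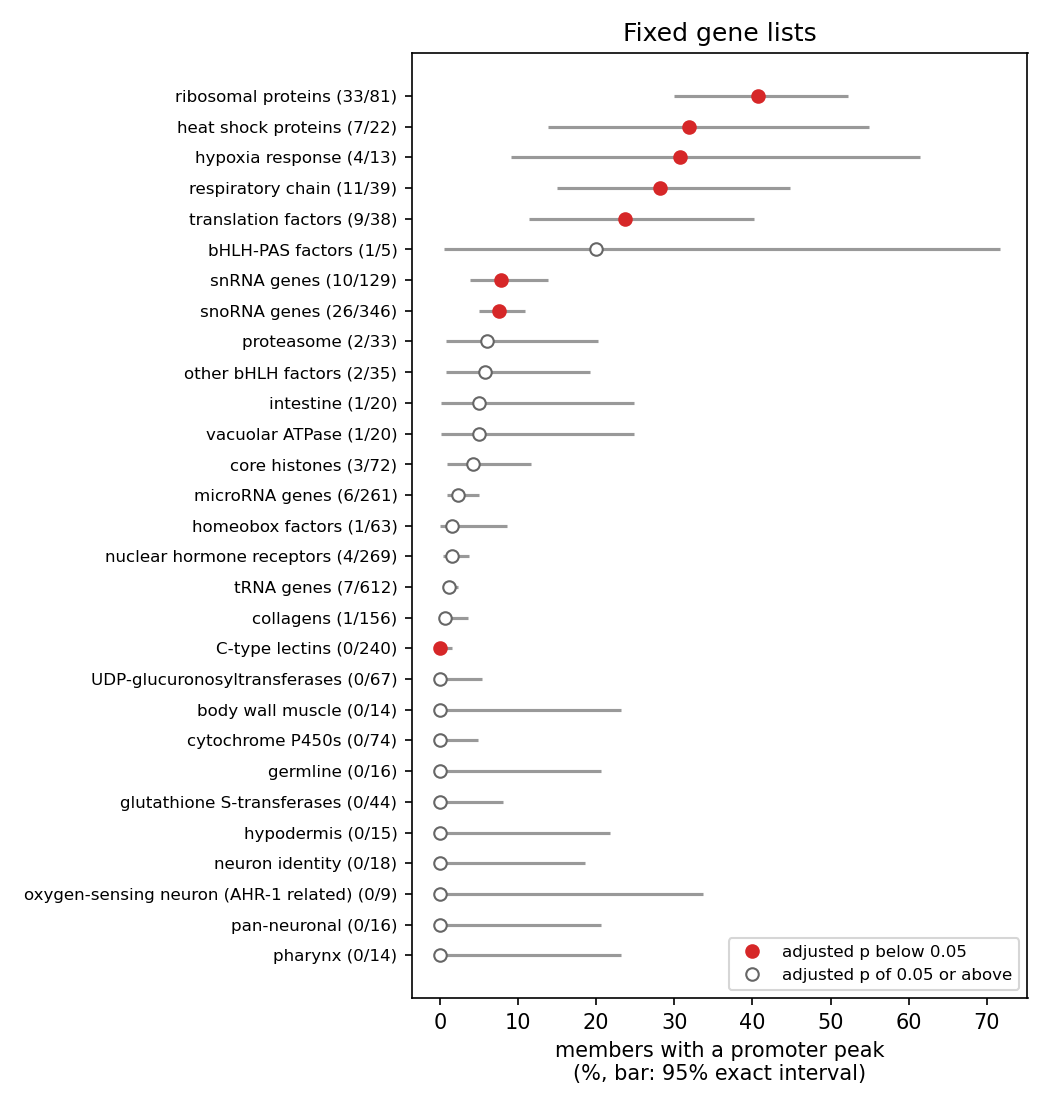
Share of the members of each of 29 gene lists with a thresholded peak in the promoter window, in percent, with exact 95% intervals as bars and counts beside the names. Red points have an adjusted p below 0.05 and open points do not; ribosomal protein genes are at 40.7%, and C-type lectin genes, the only list called lower, at 0.

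AHA-1 peaks lay mostly in promoter windows of protein-coding genes. The summits of 377 of the 530 peaks (71.1%, interval 67.1 to 74.96%) fell in a promoter window, against a mean of 25.7% and a maximum of 30.8% over 1000 random placements within chromosomes (one-sided randomisation p 0.001, the smallest they can give). The median position of these summits was -197 bp from the start, with an interquartile range of -335 to -100 bp. The window reaches 1000 bp upstream but 200 bp downstream, so an upstream median is in part set by it. Of these summits, 155 lay in the windows of more than 1 gene, so that 546 genes had a promoter peak. Of the 377, 23 were in a window only through a start inside a gene. Among regions of the relaxed list outside the thresholded peaks, 31.1% were in promoter windows (p 2.26e-78 in a two-sided Fisher's exact test against the thresholded peaks). Coding exons outside the windows held 4 summits (0.755%, against 19.05% of random positions), introns 47 (8.87% against 27.9%), UTRs 8 (1.51% against 2.76%), non-coding genes and pseudogenes 16 (3.02% against 3.06%) and intergenic sequence 78 (14.7% against 21.5%).

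By chromosome, III held more peaks and V fewer than their share of the genome. Chromosome III had 103 peaks, 19.4% of the total (interval 16.1 to 23.1%) against 13.7% of the sequence (adjusted p 0.000918 in an exact binomial test). Chromosome V had 75, or 14.2% (interval 11.3 to 17.4%) against 20.9% (adjusted p 0.000544), although it carried the peaks at egl-9 and nhr-57. The X chromosome had 91 peaks, 17.2% against 17.7% (adjusted p 0.820), and chromosomes I, II and IV with 89, 83 and 89 did not differ from their lengths either. Measured against the share of protein-coding genes, 13.7% on X, the same 91 peaks were an excess (adjusted p 0.0453). Chromosome IV fell to 13.4% (adjusted p 0.0274) among the top peaks of replicate 2 alone.

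Both core words of ARNT dimers were found at the summits more often than beside them. GCGTG, the core of the site for the AHR dimer, was within 50 bp of 144 of 530 summits (27.2%, interval 23.4 to 31.2%) against 6.70% of windows centred 400 bp away, 4.06-fold with an adjusted p of 4.62e-17 in an exact McNemar test. ACGTG, the core of the site for the HIF dimer, was at 105 summits (19.8%, interval 16.5 to 23.5%) against 10.6%, 1.88-fold with an adjusted p of 3.14e-05. Peaks with ACGTG included those at egl-9, nhr-57, sqrd-1, rhy-1, F22B5.4 and hlh-30, and peaks with GCGTG included those at rpl-3, rpl-15, rpl-35, iff-2, cox-5A and aha-1. By list, GCGTG was at 10 of 31 ribosomal protein, 4 of 9 translation factor, 3 of 11 respiratory chain and 2 of 6 heat shock peaks. Over the 57 peaks of these 4 lists it was at 33.3% against 26.4% of the other 473, a difference that did not pass (p 0.273 in Fisher's exact test). Among the 268 thresholded peaks that were in the top 530 of both replicates, an alternative chosen after seeing the data, ACGTG was 1.64-fold and no longer passed (adjusted p 0.0916).

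GAGAGA was at 26.8% of summits against 4.72% of flanks (5.68-fold, adjusted p 1.15e-28), the highest fold of the 6 words set in advance. GCGTG had the higher fold with windows of 25 bp each side (5.41 against 4.90) and against relaxed regions (4.20 against 3.60). The palindromic E-box CACGTG was at 25 summits, 4.72% against 1.51% (3.13-fold), with an adjusted p of 0.0564 that fell to between 9.04e-05 and 0.00295 in 4 of the alternatives. The 1.51% is the mean of both flanks, whereas the McNemar test used the 1 flank drawn for each peak. For 25 peaks the word was at the summit only, and for 12 in the drawn flank only, so the p depends on that draw. Other E-boxes of the form CANNTG were at 36.8% against 28.9% (1.27-fold, adjusted p 0.00664), a call that ended with windows of 25 bp each side (adjusted p 0.185), among the top peaks of replicate 2 alone (adjusted p 0.383) and among the 268 peaks (adjusted p 0.0916). The GATA word WGATAR was at 12.8% against 18.2% (0.705-fold, adjusted p 0.0579) and was lower with windows of 100 bp each side (adjusted p 0.000362) and against relaxed regions (adjusted p 2.65e-05). Of all 2080 words of 6 bp, 337 were more frequent and 290 less frequent at the summits. GACGCA had the smallest p, with 24.5% of summits against 2.17% of flanks (11.3-fold, adjusted p 5.25e-27), followed by GAGAGA and by ACGCAG (22.1% against 2.45%). None of these leading words holds GCGTG or ACGTG on either strand. GACGCA and ACGCAG overlap in sequence, so they may mark the same sites. Words such as AAAATT (15.1% against 41.9%) were depleted, and the G+C content was 49.0% at summits, 36.4% in flanks and 35.4% in the genome.

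**Figure D4:**
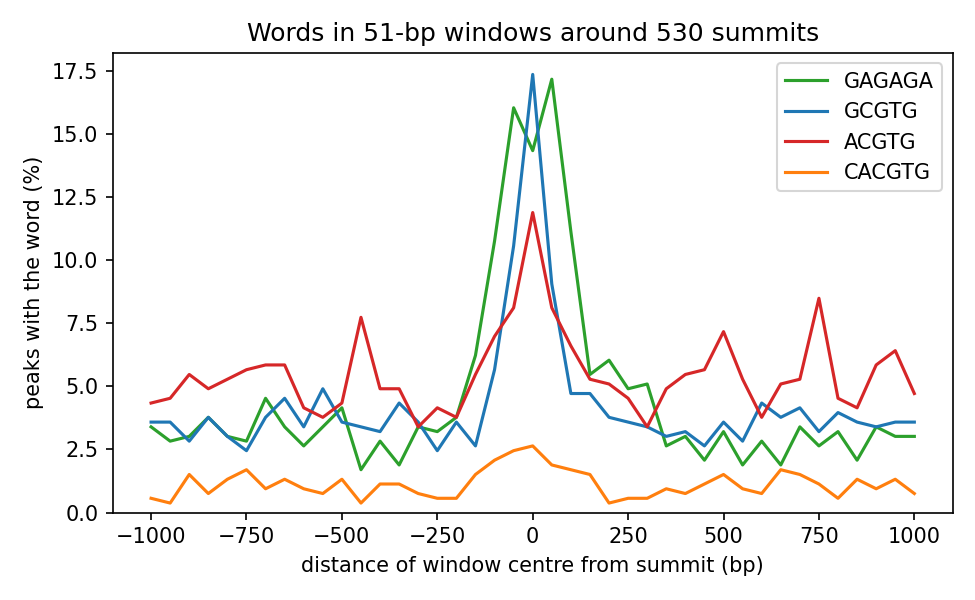
Share of the 530 thresholded peaks with GAGAGA, GCGTG, ACGTG or CACGTG in 51-bp windows, in percent, by the distance of the window centre from the summit in bp. All 4 words are most frequent within 50 bp of the summit.

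The egl-9, nhr-57, rpl-3, hlh-30, rpl-15 and sqrd-1 peaks were near the top of both replicate lists, and overlap between the lists was far above random placement. Of the top 530 regions of each replicate by signal, 273 (51.5%, interval 47.2 to 55.8%) overlapped one of the other by at least 1 bp, against a mean of 0.332% and a maximum of 1.32% in 1000 random placements (one-sided randomisation p 0.001, the smallest they can give). All 530 thresholded peaks overlapped a region listed in replicate 1 and 504 overlapped one in replicate 2. They were in the top 530 of replicate 1 in 425 cases (80.2%), of replicate 2 in 352 (66.4%) and of both in 268 (50.6%). Across the 504 peaks listed in both, which are not independent replicates, the signal values had a Pearson r of 0.665 and a Spearman rho of 0.271. Without the peaks at egl-9 and nhr-57, r was 0.509, and among the stronger peaks, taken as the 265 of highest pooled signal, rho was 0.115. Both the 530 and the 265 peaks were chosen by pooled signal, which derives from both replicates. Such a choice can itself lower a correlation between replicates, so these values do not measure agreement over all regions. The aha-1, hif-1 and F22B5.4 peaks ranked 7047, 1515 and 976 in replicate 2, and were thus outside its top 530.

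Promoter position and the words were concentrated at the top of the relaxed list of 30000 pooled regions. Its strongest 6000 regions were in promoter windows in 43.8% of cases (interval 42.5 to 45.1%), and the next 4 sets of 6000 in 30.03, 29.02, 27.8 and 28.1%. GCGTG was at 12.2% of the strongest set and 5.20 to 5.95% of the others, ACGTG at 12.95% and 7.88 to 8.87%, and GAGAGA at 14.5% and 5.60 to 7.48%. In 10 sets of 3000, the strongest had 53.2% in promoter windows.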

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

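The alternatives restricted to the 268 peaks in the top of both replicates, to genes with a relaxed region, to the outermost start of each gene and to a correlation without the 2 strongest peaks were chosen after seeing the data. Of the values that answer a comparison, 141 kept their direction and side of the threshold or stayed within their interval, 9 lost and 6 gained a call, 6 moved and 1 reversed. The promoter share stayed above random placement in each of its alternatives, and the random share moved with the window. It was 60.0% against 13.9% with 500 bp upstream and 100 bp downstream, 80.4% against 45.8% with 2000 and 500 bp, 80.8% against 37.7% with the starts of all genes and 66.8% against 20.999% with outermost starts, beside 71.1% against 25.7%. GCGTG and GAGAGA stayed above their reference in each alternative. The hypoxia (23.1 to 50% of members), ribosomal (20.99 to 45.8%), translation factor (13.2 to 33.3%), respiratory chain (17.9 to 35.5%), snoRNA (3.47 to 12.8%) and snRNA (3.88 to 17.5%) lists passed in each. Their highest shares were among genes with a relaxed region, where fewer genes were counted. Among the 265 or 268 peaks their shares were lower than in the main test, and so were the shares of other genes. With nearest starts only, the ribosomal share was 23.5%, the respiratory chain share 17.9% and the snoRNA share 3.47%. The number of peaks was 265 for the stronger peaks and 268 for those in the top of both replicates, by construction. Replicate overlap was 55.8% for the top 265 and 43.9% for the top 1060 regions. Spearman rho was 0.115 for the stronger peaks, a choice by pooled signal that can itself lower it. On X, 17.2% of peaks went from below the length share to above the gene share (adjusted p 0.0453). The cause was not tested for the changes that follow. CACGTG passed with 100 bp windows (2.68-fold) and against relaxed regions (2.50-fold), and ranged from 3.00 to 3.47-fold without 1 replicate, passing both times. WGATAR passed as lower with 100 bp windows (0.690-fold) and against relaxed regions (0.638-fold). Other CANNTG words no longer passed with 25 bp windows (1.31-fold) or among the 268 peaks (1.29-fold), and ranged from 1.13 (without replicate 1, not passing) to 1.37-fold. ACGTG was 1.64-fold and no longer passed among the 268 peaks. The C-type lectin share was 0 with the stronger peaks, the 268 peaks and genes with a relaxed region, none passing, and 0 to 0.417% without 1 replicate, not passing at the upper value. Heat shock genes were at 13.6% with nearest starts only and no longer passed. The strongest of 10 sets of relaxed regions had 53.2% in promoter windows. Read depth, which would limit how many weak sites can be called, is unknown.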

Other observations

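The comparisons in this and the next paragraph, and the choice of genes and chromosomes for them, were made after the main results were seen. All 4 promoter peaks of the hypoxia list (nhr-57, sqrd-1, rhy-1 and F22B5.4) had ACGTG within 50 bp of the summit, against 19.2% of the other 526 peaks, and 0 of the 4 had GCGTG, against 27.4%. These counts describe 4 peaks picked after the results were seen, and no p is given for them. The egl-9 peak, which lies outside the promoter window, also had ACGTG, and the peak 1967 bp upstream of hif-1 had neither word. Of the 10 strongest peaks, 5 had ACGTG (egl-9, nhr-57, the ZK470.4 region, hlh-30 and sqrd-1) and 5 had GCGTG (the ZK470.4 region, rpl-3, rpl-15, tasp-1 and iff-2), with 1 in both sets. Over all 530 peaks the words were not found to exclude each other: 25 of the 105 peaks with ACGTG also had GCGTG, and 306 peaks had neither (p 0.462 in Fisher's exact test). Of the 8 extensions of the core by 1 base, 3 passed among all words of 6 bp, namely TACGTG (8.11% of summits against 2.55% of flanks, adjusted p 0.000246), ACGTGC (8.30% against 2.36%, adjusted p 0.000344) and ACGTGA (7.36% against 3.68%, adjusted p 0.00481). AACGTG, CACGTG, GACGTG, ACGTGG and ACGTGT did not pass (adjusted p 0.732, 0.120, 0.494, 0.282 and 0.613).

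Of the 6 chromosomes, X had the lowest share of its peaks in promoter windows. Of 91 peaks on X, 46 were in promoter windows (50.5%, exact interval 39.9 to 61.2%), against 331 of 439 on the autosomes (75.4%), while the windows covered 21.8% of X and 27.2% of the autosomes. With each chromosome tested against the other 5, X passed (adjusted p 3.60e-05 over 6 tests in Fisher's exact test) and the autosomes, from 68.5 to 79.8%, did not (lowest adjusted p 0.163). ACGTG was less frequent at promoter peaks (16.98% of 377) than at the other 153 peaks (26.8%, adjusted p 0.0176 over 3 words), as was GAGAGA (22.3% against 37.9%, adjusted p 0.00101), and GCGTG showed no difference that passed (29.2% against 22.2%, adjusted p 0.107).

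The tests that follow were set before the values they measure were computed, but the housekeeping set in the next paragraph was picked after the gene lists had been tested, and the tests of GCGTG at those genes, against other promoter summits and across the relaxed list were chosen after the results were seen. Transgenes of this kind carry the tagged gene with flanking sequence, and additional copies of the aha-1 locus could raise signal around that gene. Within 15 kb of the aha-1 start the pooled relaxed list had 3 regions, against a median of 9 around protein-coding starts (percentile 2.90). The percentiles were 61.3 in replicate 1 and 45.3 in replicate 2, so the number of called regions was not raised there. Only regions were counted, so whether copies raised the signal of a region, such as the aha-1 peak, was not tested. Copies present in the control as well would not raise these counts, and the strain of the control was not given in the sources used here. The counts therefore do not decide whether extra copies were present.

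Peaks at ribosomal protein, translation factor, respiratory chain and heat shock promoters may reflect AHA-1 binding or a tendency of active promoters to give peaks, and the design has no second group that would test a biological explanation. Strong transcription alone, if it acted on all classes, needed tRNA genes above an odds ratio of 2 as well. The value was 0.674 (interval 0.269 to 1.40), against 26.0 for ribosomal protein genes. These ratios have unlike backgrounds: all other genes for tRNA genes (1.69% with a peak) and other protein-coding genes for ribosomal protein genes (2.58%). Reads of near-identical tRNA copies can also be lost, and transcription was not measured here. This explanation therefore stays open for protein-coding genes. For promoters rich in GAGAGA, the comparison set in advance gave a lower share at these peaks than at the other summits. It cannot decide the question, because the other summits include 153 outside promoters. GAGAGA was more frequent at those 153 (37.9%) than at promoter peaks (22.3%). The word was at 14.04% of the 57 summits (interval 6.26 to 25.8%), all in promoters. It was at 28.3% of the other 473 (p 0.0256 in Fisher's exact test), a set that includes summits outside promoters. Against the other 320 promoter summits, a comparison chosen after the results were seen, the share was also lower but did not pass (23.8%, p 0.121). The share at the 57 summits was above the 4.72% of flanks, so this explanation stays open. Binding through ACGTG was neither shown nor excluded, with 10.53% of the 57 summits (interval 3.96 to 21.5%) against 20.9% of all others and 18.1% of the other promoter summits (p 0.184). GCGTG was at 33.3% of the 57 (interval 21.4 to 47.1%), above flanks at 6.70% (upper bound 8.37%) as binding through it would need, but without a difference that passed from all others (26.4%, p 0.273) or other promoter summits (28.4%, p 0.527), and a part from base composition stays open.

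The excess of the core words at summits could come from base composition, since summits were richer in G+C than flanks. Of 59 other words made of the bases of ACGTG, 14 had a fold at least as high as its 1.88, and the median was 1.26. For GCGTG, 1 of 19 such words, CGCAC with 5.17-fold, exceeded its 4.06-fold, and the median was 2.04. Both words were above the median and neither was above every permuted word, so a part from composition cannot be told apart from a part from the words themselves. The design has no second group that would test a biological explanation of this excess.

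A further hypothesis was that ACGTG becomes more frequent with signal value. Within the thresholded peaks it was at 25% of the 132 strongest and 18.1% of the other 398 (p 0.101 in Fisher's exact test), which neither shows nor excludes it there. Across the relaxed list it was more frequent at the top, at 12.95% of the strongest 6000 regions (interval 12.1 to 13.8%) and 7.88 to 8.87% of the other 4 sets, whose upper bounds reached 9.61%. The regions of rank 531 to 6000, without the thresholded peaks, had 12.3% (interval 11.4 to 13.2%). What sets this difference was not tested.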
